A study of Mus musculus with 96 samples.

How the data were processed

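Single metaphase II (MII) oocytes and single blastomeres of 2-cell embryos were profiled by RNA sequencing in a mouse line with a variant of Padi6, P620A, in the protein it encodes. The labels give 22 libraries to wild-type oocytes, 22 to oocytes homozygous for the variant, 22 to wild-type 2-cell blastomeres, 22 to 2-cell blastomeres that inherited the variant from the mother, and 8 to negative controls. Per the labels' protocols, cumulus cells were removed with hyaluronidase, 2-cell embryos came from in vitro fertilisation, polar bodies were discarded, and polyadenylated RNA was captured on beads after its separation from DNA. It was copied to cDNA with template switching, amplified by PCR and made into libraries by tagmentation. The protocols name no molecular identifiers.

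The deposited table holds raw gene counts per library, in whole numbers with no normalization. The authors trimmed reads with Trim Galore 0.4.4, aligned them with HISAT2 2.1.0 to GRCm39 and used DESeq2, for which no version is given, per the submitters' processing notes. Its 36983 gene entries carry symbols only, and 48 entries that repeated a symbol were summed into it, which left 36935 symbols. Of these, 33912 were found in the reference gene table. Each of the 96 columns carries a label number, a stage and a genotype, and 0 columns lacked a matching sample. No coordinates were used, because the annotation at hand is of an earlier genome build.

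Libraries were grouped by their labels alone. A library was kept with at least 100000 gene counts and at least 4000 genes with a count. This kept 19 of 22 libraries labelled wild-type oocyte, 19 of 22 labelled mutant oocyte, 14 of 22 labelled wild-type 2-cell and 21 of 22 labelled mutant 2-cell. Doublets were not searched for, since each library was made from 1 picked cell. Genes per library were also counted after thinning each kept library to 100000 counts.

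The level of a gene in a group was its counts summed over the kept libraries, divided by their summed totals, in counts per 1000000 (CPM). Groups were compared by the ratio of these pooled levels, with an exact conditional binomial 95% interval for the ratio and an exact Poisson interval for a level. Libraries of 1 cell are not replicates of an animal, and the labels name no animal, so each group counted as 1 sample, no test was run and no p-value is given. PCR reads without molecular identifiers are not independent molecules, so every interval and floor covers counting error only. Genes were compared when the pooled level was at least 10 CPM in at least 1 of the groups and a count was present in at least 50% of the kept libraries of the group with the higher level. A gene was counted as higher or lower at a ratio of at least 2. A group with no counts was set to a floor of 3 counts over the group, which makes the ratio a lower bound.

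There were 4 comparisons: mutant over wild type among libraries labelled oocyte, the same among libraries labelled 2-cell, and 2-cell over oocyte within each genotype label. The genes named were chosen by rule: Padi6 first; for each genotype comparison the 12 genes with the largest and the 12 with the smallest ratio, and for each stage comparison 8 each way, among genes with a proper gene name that differed at least 2-fold and whose per-library medians, each with 1 CPM added, differed at least 1.5-fold the same way; and up to 4 members of each gene list with the largest ratio either way. The text gives a part of these. Mos and Zfp352 levels per library, and the level of 100 CPM of Mos, were chosen after the values were seen. Comparisons, filters, gene lists, the naming rule and the 10 alternative settings were fixed before the data were examined.

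The 21 gene lists cover the subcortical maternal complex and cytoplasmic lattice, oocyte maternal genes, 2-cell activation genes, early embryo transcription factors, nucleolus and ribosome biogenesis, RNA polymerase II subunits, splicing factors, proteasome subunits, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded protein genes, maternal mRNA clearance factors, DNA methylation and heterochromatin, imprinted genes, cell cycle and spindle checkpoint, p53 targets and DNA damage, heat shock and integrated stress response, cytoskeleton, and markers of cumulus and granulosa cells, sperm and blood cells. Each list was described by its median log2 ratio, an order-statistic interval over its genes, and the percentile of that median among 10000 random lists of the same size matched on mean level in 20 bins. Genes at least 4-fold higher ("activated") or lower ("cleared") in odd-numbered libraries labelled wild-type 2-cell than in those labelled wild-type oocyte were compared between the libraries labelled mutant 2-cell and the even-numbered ones labelled wild-type 2-cell, so that no 2-cell library both chose and measured a gene. Log2 ratios at both stages were correlated across genes, which are not independent replicates.

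Alternatives changed 1 choice at a time: no filter on libraries; a stricter filter of 500000 counts and 8000 genes; the mean or the median of per-library CPM; TMM factors from edgeR 4.0.16 on the pooled sums; DESeq2 1.42.0 size factors per library; totals without mitochondrially encoded genes and the 50 most abundant genes; libraries thinned to 100000 counts; a gene filter of 1 CPM; and no gene filter beyond 10 summed counts. Leaving out each library in turn, and libraries 61 and 86 together, was added after the results were seen.

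The method was tested on simulated counts with 50 genes altered by each fold in each direction. All libraries of both groups were drawn from the pooled means of the second group, with the real totals and an assumed spread between libraries. The labelled groups hold libraries of unlike contents, which the simulation leaves out. Its rates therefore describe the calculation and not the error in these data. For mutant over wild-type oocytes, 100.0% of genes 4-fold higher and 100.0% of genes 4-fold lower were recovered, 84.0% of those 3-fold higher and 96.0% of those 3-fold lower, and 45 of 8498 unaltered genes passed the 2-fold size. For mutant over wild-type 2-cell, recovery was 100.0% and 98.0% at 4-fold, 90.0% and 92.0% at 3-fold, and 106 of 9393 unaltered genes passed. For 2-cell over oocyte within wild type, it was 100.0% and 100.0% at 4-fold, 96.0% and 90.0% at 3-fold, with 98 of 8488 passing. For 2-cell over oocyte within the mutant, it was 100.0% and 96.0% at 4-fold, 92.0% and 96.0% at 3-fold, with 40 of 8379 passing. Kept libraries were also checked for repeated columns: the closest pair, libraries 49 and 57, differed by a chi-square of 6.33 per degree of freedom, where 1 stands for counting error alone. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3, were used.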

Results

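RNA levels were measured in 96 libraries, 88 of them labelled as single oocytes or single 2-cell blastomeres and 8 as negative controls. Gene counts per library ranged from 33137 to 4212825 (median 2501967) for the label wild-type oocyte and from 24 to 3185910 (median 1796969) for mutant oocyte. They ranged from 456 to 4446517 (median 2017677) for wild-type 2-cell and from 309429 to 4323022 (median 1483032) for mutant 2-cell. Kept libraries of these groups held a median of 11735, 10370, 14609 and 11160 genes with a count, and 8067, 7647, 9050 and 8231 genes after thinning to 100000 counts.

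The libraries labelled negative control held from 542 to 5762563 counts, with a median of 1126011, and 6 of 8 passed the filter for cell libraries. Those 6 had a median of 10589 genes, or 7987 after thinning, and Padi6 at 4277 CPM in the pool. The background of a well without a cell can therefore not be read from the libraries that carry this label.

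**Figure D1:**
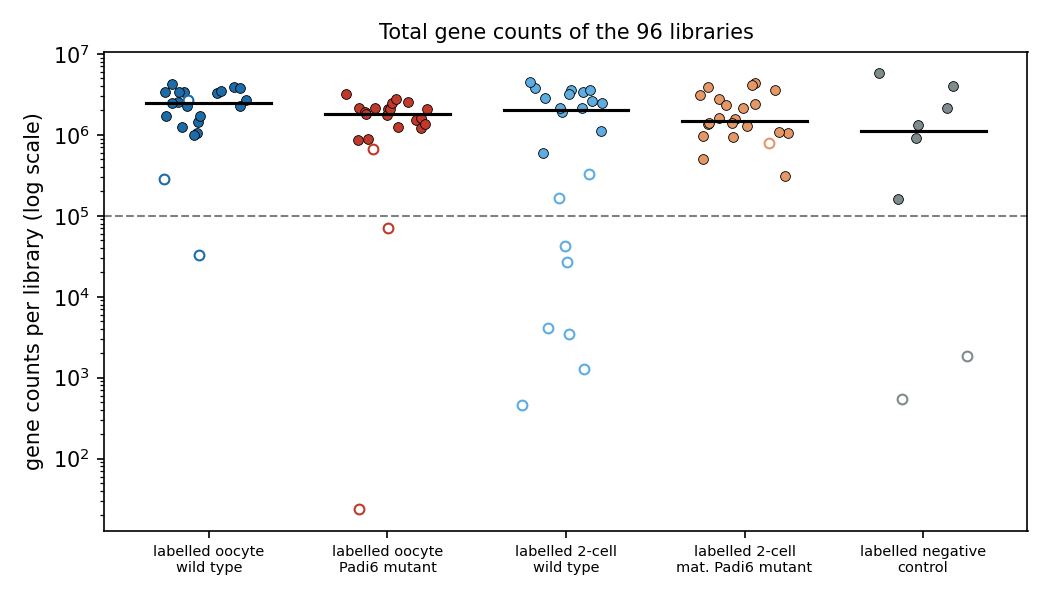
Total gene counts (log scale) of each of the 96 libraries by label, with filled points for kept libraries, open points for those left out, bars at the median of all libraries of a label and a dashed line at 100000 counts. Of the 8 libraries labelled negative control, 6 lie above the line, from 162539 to 5762563 counts.

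Padi6 encodes an oocyte protein of the cytoplasmic lattices that is needed for development beyond the 2-cell stage. Its pooled level was 3166 CPM (counting interval 3150 to 3182, 19 libraries) under the label wild-type oocyte and 224 CPM (219 to 229, 19 libraries) under mutant oocyte. It was 4608 CPM (4586 to 4630, 14 libraries) under wild-type 2-cell and 2882 CPM (2865 to 2898, 21 libraries) under mutant 2-cell. Library medians in that order were 2380, 199.9, 4750 and 339.5 CPM. The variant alters the protein and not the gene's dose, so the level of Padi6 does not check the genotype labels.

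Genes that mark the stage went against many labels. Mos, the kinase that holds the oocyte at metaphase II and whose RNA is cleared after fertilisation, reached 100 CPM in 14 of 14 kept libraries labelled wild-type 2-cell (exact binomial interval 76.8% to 100.0%) and in 0 of 19 labelled mutant oocyte (0 to 17.7%). It did so in 12 of 19 labelled wild-type oocyte (38.4% to 83.7%), in 9 of 21 labelled mutant 2-cell (21.8% to 66.0%) and in 4 of 6 kept negative controls. Zfp352, a gene transcribed at the 2-cell stage and silent in oocytes, reached 10 CPM in 17 of 19 libraries labelled mutant oocyte and in 0 of 14 labelled wild-type 2-cell, where a count of 0 allows up to 0.0976 CPM. It did so in 7 of 19 labelled wild-type oocyte and in 11 of 21 labelled mutant 2-cell. Of the 73 kept libraries of the 4 cell groups, 49 had a Mos level on the other side of 100 CPM from their stage label. Groups are therefore named by label throughout, and each direction given describes the libraries that carry a label, not a stage or genotype known to be right.

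**Figure D2:**
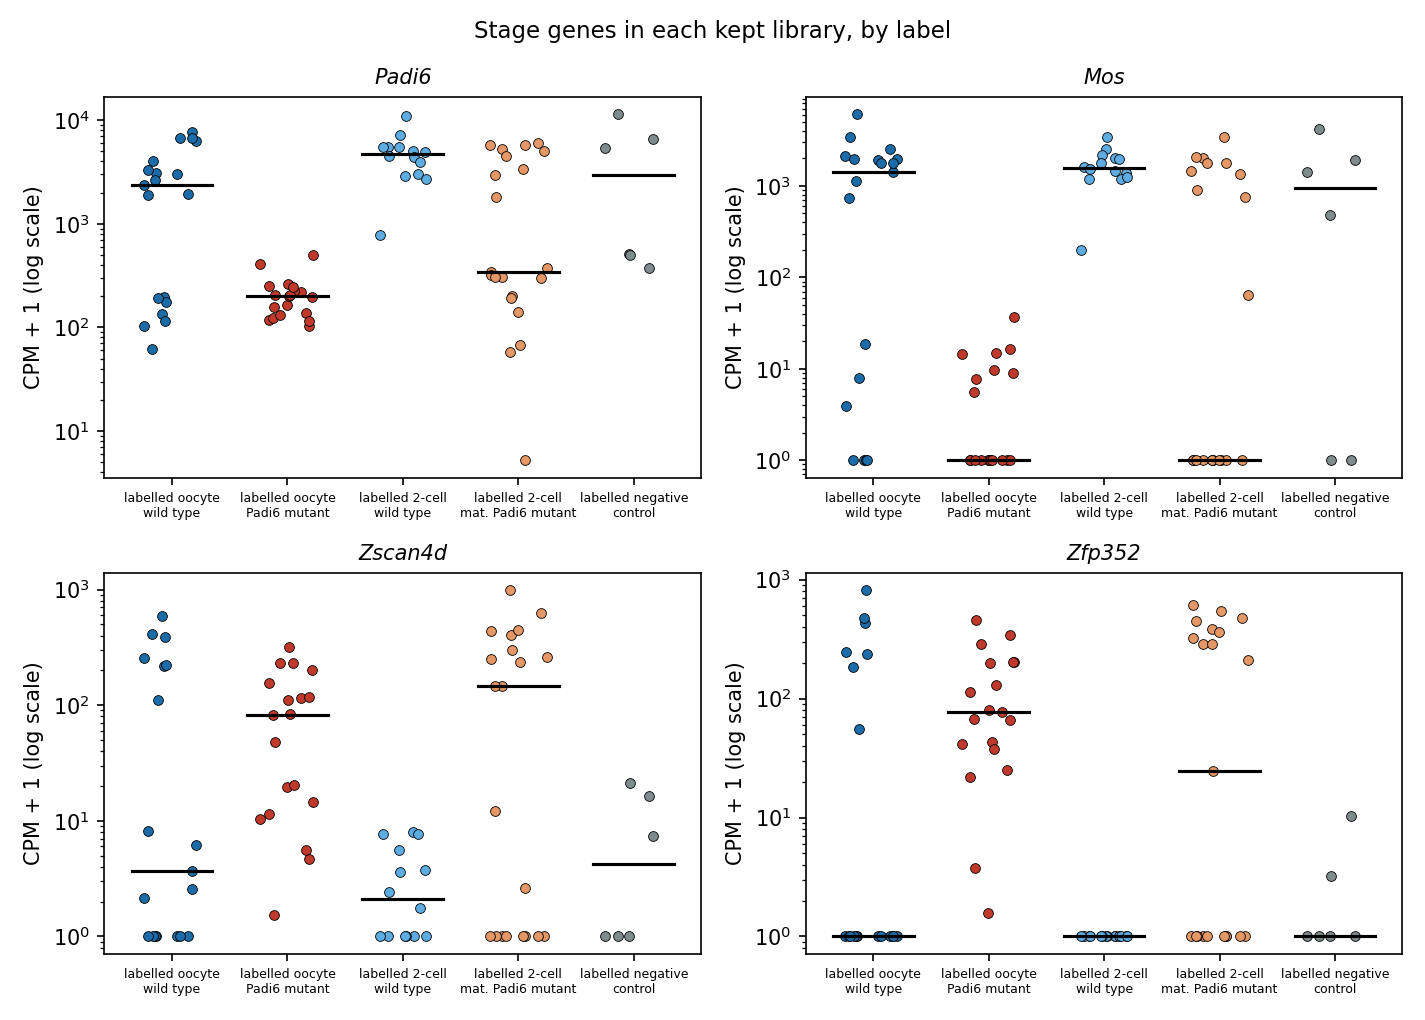
CPM plus 1 (log scale) of Padi6, Mos, Zscan4d and Zfp352 in each kept library by label, with bars at the median. Mos lies at or above 200.6 CPM in every library labelled wild-type 2-cell and below 100 CPM in every library labelled mutant oocyte, while Zfp352 shows the opposite order.

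Mutant over wild type among libraries labelled oocyte asked which stored transcripts differ in the ovulated oocyte with the variant. Mos was 301-fold lower (262 to 347), at 5.71 against 1717 CPM, though 7 of 19 wild-type libraries lay within the mutant range of 0 to 35.99 CPM. Padi6 was 14.2-fold lower (13.8 to 14.5), H1f8, the oocyte linker histone, 12.6-fold lower at 785 CPM, and Gdf9, a growth factor secreted by oocytes, 8.49-fold lower at 575 CPM. The libraries labelled wild type were not alike: 12 of 19 had Padi6 above every mutant one, and 7 had it from 61.4 to 194 CPM, below the mutant median of 199.9. Bub1b, a spindle checkpoint kinase, was 52.5-fold lower (82.8-fold without library 43). Dnmt1, the maintenance DNA methyltransferase, was 12.1-fold lower, Pabpn1l, which binds poly(A) tails in oocytes, 13.5-fold and the chaperone Hsp90aa1 9.54-fold. Pou5f1, a pluripotency factor, was 3.14-fold higher at 1034 CPM. Each of these ratios rests on part of the wild-type label: 7 of 19 libraries lay within the mutant range for Gdf9, Bub1b, Pabpn1l, Hsp90aa1 and Pou5f1, 6 for Dnmt1 and 5 for H1f8. Of 9122 genes compared, 1530 were at least 2-fold higher and 2075 at least 2-fold lower, with a median log2 ratio of -0.0053 over all genes. Higher genes made 42.4% of this split, and 32.0% (981 higher, 2082 lower) with DESeq2 size factors, which moved the median of all genes by -0.13.

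The 2-cell activation genes, a set transcribed in a burst in the 2-cell embryo, were at least 2-fold higher in 21 of 34 members under the label mutant oocyte, with a median log2 ratio of 1.39 (0.94 to 1.69) and percentile 100 among random lists. Their share of counts was below that of every mutant library in 12 of 19 wild-type ones, yet above the mutant median of 0.186% in the other 7 (0.197% to 0.716%). Eif1ad6 was 5.44-fold higher at 58.4 CPM, though genes of this family share near-identical sequence and their single values are uncertain. The 12 mitochondrially encoded genes measured had a median of 1.38 (percentile 99.99), with mt-Nd2 3.73-fold and mt-Co1 3.12-fold higher, and took 2.26% of counts in the median library against 0.359%. Again 12 of 19 wild-type libraries lay below every mutant one, and the other 7 within the mutant range, at 1.99% to 3.24%. Subcortical maternal complex genes, which organise the egg's outer cytoplasm, had a median of -1.09 (percentile 0.54), with Nlrp5 4.27-fold and Nlrp14 4.01-fold lower, while 8 and 13 of 19 wild-type libraries lay within the mutant range of these genes. Oocyte maternal genes had a median of -0.56 (percentile 0.21), or -0.32 without library 28. Proteasome subunits had one of -0.69 (percentile 0.12), or -0.16 without library 17. For the maternal complex the median library share was nonetheless 2.19% against 2.00%, with Zbed3 alone at 21760 CPM in the pool of the mutant label.

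Cytosolic ribosomal protein genes had a median log2 ratio of -1.71 and nuclear-encoded oxidative phosphorylation genes one of -1.60, both at percentile 0, which became -0.58 and -0.86 without library 17. For each of these lists only 4 of 19 wild-type libraries had a share of counts above every mutant one. Markers of cumulus and granulosa cells, the somatic cells around the egg, had a median of -3.22 (percentile 0) and were at least 2-fold lower in 11 of 12 members. Their share was above that of every mutant library in 12 of 19 wild-type ones and within the mutant range in the other 7. Vcan, a matrix proteoglycan of the cumulus, had 0 counts under the label mutant oocyte and was at least 477-fold lower (at least 306-fold without library 16 and at least 292-fold without library 17). Hsd3b1, a steroid-making enzyme, stood at 0.0560 against 292 CPM, 5225-fold lower (1446 to 43150), and this rested on 2 counts. It was 2358-fold lower without library 17. Without library 32 the mutant label stood at the floor, and Hsd3b1 was at least 3282-fold lower. Other lists had medians within the central 95% of random lists: early transcription factors 0.04, nucleolus -0.09, RNA polymerase II 0.08, splicing -0.25, clearance factors -0.12, DNA methylation -0.30, imprinted genes -0.22, cell cycle -0.23, p53 targets 0.16, stress response -0.31 and cytoskeleton 0.01. Of the sperm markers only Oaz3 passed the gene filter, 2.18-fold higher (1.87-fold without library 27, 1.99-fold without library 31), and of the blood markers 0 did.

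Outside the lists, the genes with the largest ratios included Duoxa2, a maturation factor of a dual oxidase, at 88.8 against 2.47 CPM, 35.9-fold higher (29.9 to 43.4; 101-fold without library 6). Duoxa1, which encodes a related maturation factor, was 41.2-fold higher (110-fold without library 6). Fbxl8, an F-box protein gene, was 16.4-fold higher (13.3 to 20.4) and the keratin gene Krt73 18.3-fold (35.7-fold without library 20). The number of mutant libraries above every wild-type one was 8 for Duoxa2, 10 for Duoxa1, 11 for Fbxl8 and 12 for Krt73, of 19.

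Mutant over wild type among libraries labelled 2-cell asked how the maternal variant affects transcripts of the early embryo. The 2-cell activation genes were at least 2-fold higher in 29 of 31 members, with a median log2 ratio of 8.35 (7.21 to 9.00, percentile 100) in which members with no counts stand at their bound. The difference came from 11 of 21 mutant libraries, in which these genes took 0.278% to 1.19% of counts; the other 10 had at most 0.0262%, against 0.0127% to 0.0325% under wild type. Zfp352 had 112 CPM under the label mutant and 0 counts under wild type, at least 1410-fold higher, and AF067061 166 CPM and 0 counts, at least 2087-fold higher. Tmem92, another gene of this burst, had 63.4 CPM against 0.0794 CPM, a ratio of 799 (273 to 3877) that rested on 3 counts (2232 without library 59). Pou5f1 was 3.00-fold higher at 394 CPM, and the egg factor Dppa3, which guards maternal DNA methylation, 2.51-fold higher at 4336 CPM, each with 13 of 21 mutant libraries above every wild-type one. Padi6 was 1.60-fold lower (1.59 to 1.61) in the pool, which averages over 12 of 21 mutant libraries below every wild-type one and 9 within the wild-type range. Of 9996 genes compared, 788 were at least 2-fold higher and 1181 at least 2-fold lower, and the median of all genes was -0.09. The number of lower genes was 1941 without library 86 and 410 without library 61. Per-library medians in place of pooled levels gave 461 higher and 2244 lower genes, and per-library means 1278 higher and 1236 lower.

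Mitochondrially encoded genes had a median log2 ratio of 1.69 (percentile 100), with mt-Nd1, a subunit of respiratory complex I, 4.02-fold higher at 2729 CPM. Their share of counts lay above every wild-type library in 12 of 21 mutant ones and within the wild-type range in 9. Subcortical maternal complex genes had a median of -0.56 (percentile 0.465), or -0.19 without library 53. Tle6, a partner of Nlrp5, was 1.73-fold lower (1.23-fold without library 53), though 16 of 21 mutant libraries lay within the wild-type range. Proteasome subunits had a median of -0.35 (percentile 0.34), or -0.13 without library 61. Ribosomal protein genes had a median of -0.73 (-2.41 without library 86, -0.12 without library 61) and oxidative phosphorylation genes one of -0.56 (-1.73 without library 86), both at percentile 0. Markers of cumulus and granulosa cells had a median of -1.49 at percentile 0 (-3.17 without library 86, -0.53 without library 61), and 10 of 13 members were at least 2-fold lower. Their share lay below every wild-type library in 13 of 21 mutant ones and within the wild-type range in 8. Thbs1, an adhesive glycoprotein of the matrix, was 17.0-fold lower (4.41-fold without library 61, 30.2-fold without library 87), and Col4a2, a basement membrane collagen, 11.9-fold (3.63-fold without library 61, 21.3-fold without library 87). The 2 blood markers compared were lower, Lyz2, the macrophage lysozyme, by 16.5-fold (6.83-fold without library 55, 39.7-fold without library 86) and Cd52 by 6.49-fold (1.57-fold without library 61, 30.0-fold without library 86).

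Remaining lists lay within the central 95% of random lists: maternal genes -0.03, early transcription factors 0.02, nucleolus 0.16, RNA polymerase II 0.16, splicing -0.07, clearance factors -0.12, DNA methylation -0.02, imprinted genes 0.19, cell cycle -0.17, p53 targets -0.21, stress response -0.19 and cytoskeleton -0.19. Among their members, Ddit3, a stress-induced transcription factor, was 2.53-fold higher and Gmnn, an inhibitor of replication licensing, 2.07-fold higher (1.88-fold without library 61, and below 2-fold without any 1 of 5 others). Xbp1, a regulator of the unfolded protein response, was 3.06-fold lower (5.39-fold without library 86). No sperm marker passed the gene filter.

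**Figure D3:**
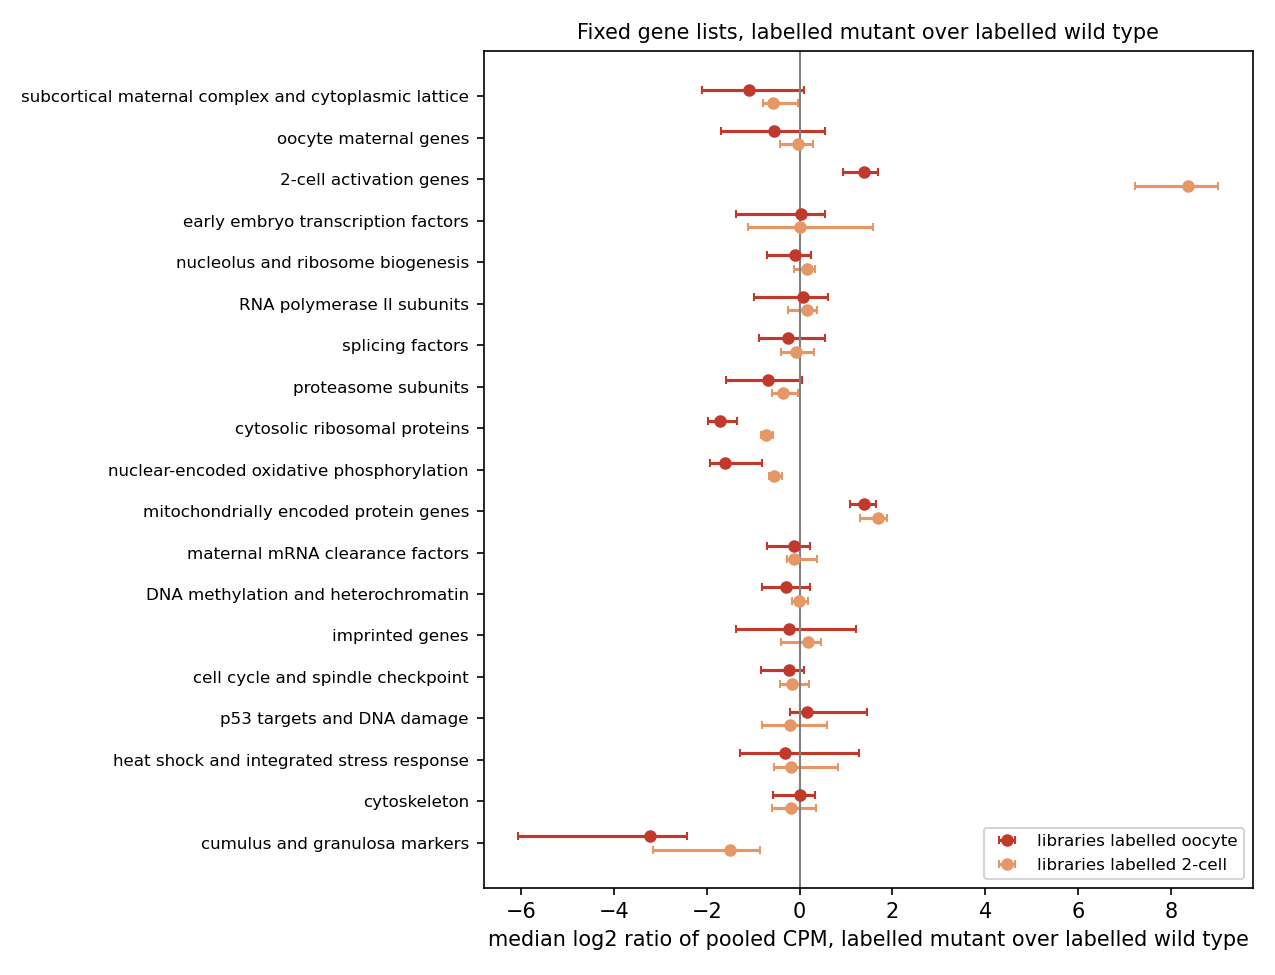
Median log2 ratio of pooled CPM, labelled mutant over labelled wild type, for 19 gene lists in libraries labelled oocyte (red) and 2-cell (orange), with order-statistic 95% intervals over genes. The 2-cell activation genes lie at 1.39 and 8.35, and the mitochondrially encoded genes at 1.38 and 1.69.

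The genes chosen in the odd-numbered libraries labelled wild-type 2-cell asked whether activation and clearance after fertilisation differ with the maternal variant. Of 987 genes at least 4-fold higher in those 8 libraries than under wild-type oocyte, 443 were compared, with a median log2 ratio of -0.49 (-0.58 to -0.40, percentile 0) for 21 mutant libraries over 6 even-numbered wild-type ones. Of these, 15 were at least 2-fold higher and 111 at least 2-fold lower. The direction rested on library 60: the median was 0.15 without it, and -1.44 without library 86. Library 61, with 1.14% of its counts in cumulus and granulosa markers, was among the 8 that chose the genes. Without library 61, 708 genes in place of 1701 were at least 2-fold higher for 2-cell over oocyte within the wild-type label. Of 84 genes at least 4-fold lower, 74 were compared, with a median of 3.24 (2.66 to 3.76, percentile 100), 68 at least 2-fold higher and 0 lower. That median was 2.42 without library 53 and 2.55 without library 51. Since Mos passed 100 CPM in each kept library labelled wild-type 2-cell, neither set is known to hold genes of zygotic activation or maternal clearance. Mos lay below 100 CPM in 7 of 19 libraries labelled wild-type oocyte and in 12 of 21 labelled mutant 2-cell. The median of the cleared set can follow from this mix alone, so it does not measure an effect of the variant on clearance.

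2-cell over oocyte within the wild-type label asked which transcripts differ between the stages. Zscan4d, a 2-cell burst gene, was 30.8-fold lower (24.9 to 38.5) under the label 2-cell, at 2.33 against 71.7 CPM, in a family whose copies share reads. Only 8 of 19 oocyte libraries lay above every 2-cell one. Pnpla3, a lipase gene, was 82.9-fold lower (191-fold without library 53), and Hormad1, a meiotic chromosome axis gene, 31.6-fold lower (51.6-fold without library 60). Pou5f1 was 2.51-fold lower, with 10 of 19 oocyte libraries above every 2-cell one and 9 within the 2-cell range. Padi6 was 1.46-fold higher, with 7 of 19 oocyte libraries below every 2-cell one and 12 within the 2-cell range. Hsd17b1, a granulosa oestrogen enzyme, was 20.3-fold higher (8.30-fold without library 61, 34.8-fold without library 16). Of 9688 genes compared, 1701 were at least 2-fold higher (708 without library 61) and 354 lower, with a median of 0.14. Higher genes made 82.8% of this split, 70.3% (1345 higher, 569 lower) with TMM factors and 60.3% (1193 higher, 787 lower) with DESeq2 size factors, which each moved the median of all genes by -0.20.

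Among the lists within the wild-type label, 2-cell activation genes had a median of -2.04 over 9 members (percentile 0), which moved to between -2.68 and -2.76 when library 9, 10, 11, 12, 14, 16, 17, 18, 20 or 22 was left out. Leaving out a library can also change which members pass the gene filter. Zfp352 and Tdpoz4, at 71.0 and 22.3 CPM under oocyte and 0 under 2-cell, did not pass it. Each had 0 counts in 12 of 19 oocyte libraries. Mitochondrially encoded genes had a median of -1.08 (percentile 0), with mt-Cytb 2.77-fold lower. For both lists 7 of 19 oocyte libraries had a share of counts above every 2-cell one. Ribosomal protein genes had a median of 0.99 (2.09 without library 17, 0.37 without library 61), oxidative phosphorylation genes 0.77 (1.52 without library 17), proteasome subunits 0.36 and cytoskeleton genes 0.41, at percentiles from 99.76 to 100. Cumulus and granulosa markers had a median of 2.08 at percentile 100 (0.82 without library 61, 2.73 without library 17). Lists within the central 95% were the maternal complex at 0.07, maternal genes -0.08, early transcription factors -0.01, nucleolus 0.13, RNA polymerase II 0.17, splicing 0.13, clearance factors -0.11, DNA methylation -0.13, imprinted genes -0.03, cell cycle 0.0032, p53 targets 0.58, stress response 0.22 and 2 blood markers 1.79. The median of p53 targets was 0.14 without library 61. Each blood marker rested on 1 library: Cd52 was 4.79-fold higher (1.16-fold without library 61) and Lyz2 2.49-fold (1.03-fold without library 55).

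2-cell over oocyte within the mutant label put the same question to embryos of mutant mothers. Padi6 was 12.9-fold higher (12.6 to 13.2) under the label 2-cell, H1f8 10.3-fold higher at 8098 CPM, Gdf9 8.16-fold higher at 4696 CPM and Dnmt1 10.7-fold higher at 457 CPM. For Padi6 this rested on 9 of 21 libraries labelled 2-cell, at 1796 CPM or more, above every oocyte library; the other 12 had at most 375 CPM, within or below the oocyte range of 102 to 500 CPM. The libraries above every oocyte one were 11 of 21 for H1f8 and Gdf9 and 10 for Dnmt1 and Ovgp1. Zbed3, a partner of the subcortical maternal complex, was 2.80-fold lower at 7761 against 21760 CPM, in 8 of 21 libraries below every oocyte one and in 13 within the oocyte range. Krt71, a keratin gene, was 42.0-fold lower (32.0 to 56.1) at 1.29 against 54.0 CPM. Ovgp1, an oviduct glycoprotein, was 400-fold higher (136-fold without library 86, 763-fold without library 26), and Vim, a filament gene of somatic cells, 12.5-fold higher (3.09-fold without library 86, 44.2-fold without library 27; 3 of 21 libraries above every oocyte one). Of 9164 genes compared, 2106 were at least 2-fold higher and 939 lower, with a median of 0.10.

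Subcortical maternal complex genes within the mutant label had a median of 1.01 (percentile 99.60), while their share of counts was 1.40% in the median 2-cell library against 2.19%, the lower level of Zbed3 weighing most. Oocyte maternal genes had a median of 0.28 (percentile 97.87), or 0.13 without library 91. Proteasome subunits had a median of 0.76 (0.30 without library 86) and splicing factors 0.47. Ribosomal protein genes had a median of 1.85 (0.29 without library 86), oxidative phosphorylation genes 1.68 (0.57 without library 86) and mitochondrially encoded genes -0.99. Cumulus and granulosa markers had a median of 2.69 over 7 members, 1.85 without library 86, and between 3.29 and 3.35 when library 29, 38, 73, 74, 75, 79, 80, 81, 88 or 92 was left out. Lists within the central 95% were 2-cell activation genes at -0.11, early transcription factors -0.19, nucleolus 0.33, RNA polymerase II 0.03, clearance factors 0.01, DNA methylation 0.35, imprinted genes 0.36, cell cycle 0.40, p53 targets -0.10, stress response 0.50 and cytoskeleton 0.24. The 2-cell activation genes were not alike across libraries: their share lay below every oocyte library in 10 of 21 2-cell ones, above every one in 3 and within the oocyte range in 8. The sperm marker compared had a log2 ratio of -1.14, which was under 2-fold (1.895) without library 27.

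Across 8582 genes compared at both stages, the mutant over wild-type log2 ratios had a Spearman correlation of 0.51 and a Pearson correlation of 0.41; genes are not independent, and the stages share no libraries. Of 1195 genes higher under the label oocyte and 692 under 2-cell, 368 were shared, against 96.4 for independent lists. Of 2033 and 512 lower genes, 293 were shared, against 121 for independent lists. Opposite directions held for 31 genes higher under oocyte and lower under 2-cell, and for 16 the other way. In both comparisons the mutant label holds more of the libraries with Mos below 100 CPM. These were 19 of 19 against 7 of 19 under oocyte, and 12 of 21 against 0 of 14 under 2-cell. The correlation and overlap can follow from this mix alone, so they do not measure a genotype effect shared by the stages.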

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

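The totals of the negative controls were planned, and the tests of the stage labels given here were chosen only after the results were seen.

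Libraries labelled negative control enter no comparison, and 6 of 8 held at least 100000 gene counts, where a well without a cell should hold few. The totals were 917212 in library 23, 5762563 in library 24, 2152418 in library 47, 1334810 in library 48, 1857 in library 71, 542 in library 72, 162539 in library 95 and 4038810 in library 96. Mos stood at 476, 1427, 4153 and 1917 CPM in libraries 23, 24, 95 and 96. In libraries 47 and 48 it had 0 counts, with Zfp352 at 9.29 and 2.25 CPM.

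In 49 of 73 kept cell libraries the level of Mos went against the stage label. The tables argue against RNA carried over between wells as the source of these levels, since 0 of 39 libraries with Mos at or above 100 CPM held a count of Zfp352, while 39 of the 40 below it did. Traces carried over are not excluded: 16 of the 39 held Zscan4d, at up to 11.14 CPM, and 12 of the 40 held Mos, at up to 63.31 CPM. Among the libraries labelled wild type, 21 of 33 went against their stage label. An effect of the Padi6 variant in these would itself need a wrong genotype label. Among those labelled mutant, 28 of 40 went against their stage label. There a wrong label and a biological effect of the Padi6 genotype cannot be told apart, because the genotype label itself is in doubt. A candidate explanation is sample names attached to the wrong columns: in the table's own order, which does not follow the label numbers, kept libraries above and below 100 CPM of Mos form 2 runs, against 10 along the label numbers.

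The order of the columns was then read further. The first 8 columns hold at most 42270 counts each, kept libraries with Mos at or above 100 CPM lie in columns 9 to 51, and library 86, in column 52, has neither Mos nor Zfp352. A boundary after column 52, chosen after the order was seen, leaves 44 columns on each side, next to the 44 oocytes, 44 embryos and 8 negative controls that the design states. Which cell each column holds, and its genotype, cannot be read from this, so no library was reassigned. If sample names attached to the wrong columns were the cause of the 2 runs, this could also account for the counts in the negative controls, and none of the 4 comparisons would measure the genotype or the stage.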

How the results depend on the processing

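Leaving out libraries 61 and 86 together, and each library in turn, was chosen after the results were seen. No alternative corrects the labels. Leaving out each library whose Mos level goes against its stage label would leave 0 libraries labelled mutant oocyte and 0 labelled wild-type 2-cell, so it gives no value. No paired analysis was possible because no label number occurs in more than 1 group and no test was run.

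Under the 10 other settings, 54 of 80 gene counts stayed within 1.5 times the main count and 26 did not. A similar count need not hold the same genes. For mutant over wild-type 2-cell, thinning kept 562 of the 788 higher and 739 of the 1181 lower genes. TMM factors kept 777 and 1048 of them. All 1417 values of the 144 named gene results kept their sign, and 1309 of the 1349 that start from at least 2-fold remained at least 2-fold. This steadiness is partly built in, since the genes were chosen for the size of their ratio. Genes named outside the lists also had to differ the same way in per-library medians, so their sign could not change under that setting. The 144 results cover a part of the genes chosen by rule. Of 794 list medians, 713 lay within the interval over genes of the main value; 84 changed sign, 0 of them in lists outside the central 95% of random lists.

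A gene filter of 1 CPM, which admits more genes, gave 4356 higher and 4225 lower genes for mutant over wild-type oocyte, 2898 and 2799 for mutant over wild-type 2-cell, 3832 and 1707 for the stages within wild type and 5164 and 3148 within the mutant, a median of -0.11 for activated genes and a correlation of 0.41. No gene filter gave 5994 and 5984, 4672 and 3888, 5120 and 3508, and 6867 and 4575 in that order, medians of -0.0079 for activated and 2.44 for cleared genes, and a correlation of 0.35.

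For the following, the cause was not tested. The mean of per-library CPM gave 1278 higher genes for mutant over wild-type 2-cell, 594 lower genes for the stages within wild type, -0.58 for activated genes and a correlation of 0.5711. The median of per-library CPM gave 461 higher and 2244 lower genes for mutant over wild-type 2-cell, 155 lower genes within wild type, -2.31 for activated and 1.37 for cleared genes, and a correlation of 0.5686. DESeq2 size factors gave 981 higher genes for mutant over wild-type oocyte, 787 lower genes within wild type, -1.10 for activated genes and a correlation of 0.5704. TMM factors gave 569 lower genes within wild type. Thinning gave 557 lower genes for the stages within the mutant, 591 within wild type, -0.71 for activated and 1.76 for cleared genes, and a correlation of 0.53. No filter on libraries gave 2.63 for cleared genes, and the stricter filter -0.38 for activated genes and a correlation of 0.47.

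Without libraries 61 and 86, the stages within wild type had 708 higher genes, activated genes a median of -1.45, and the correlation was 0.56. The median of activated genes, -0.49 in the main setting, was negative under all 10 of those settings, yet 0.15 without library 60. Depth limits the ratios of genes with few counts in a group: of the genes compared, 16 for mutant over wild-type oocyte, 42 for mutant over wild-type 2-cell, 1 within wild type and 3 within the mutant had 0 counts in a group and only a bound.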

Other observations

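The tests of library 86 given here were chosen only after the results were seen.

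Library 86, labelled mutant 2-cell, had somatic genes without oocyte genes: Gdf9, Oosp1, Btg4, Mos and Zfp352 had 0 counts, and Padi6 stood at 4.21 CPM. Too few counts to detect oocyte genes is excluded, since it held 2374644 counts. Gdf9 was held by library 95, labelled negative control, with 162539 counts, and by library 89, labelled mutant 2-cell, with 309429. Library 86 had 12 of the 18 fixed cumulus and granulosa markers at or above 10 CPM. The other kept libraries had a median of 3 and a highest value of 14. In library 86 Timp1 stood at 2414 and Cyp11a1 at 1542 CPM. RNA of cumulus or granulosa cells in place of the oocyte or blastomere is therefore a candidate explanation, although the protocol's hyaluronidase step and separation of blastomeres would remove such cells. It rests on part of the list. Has2, Fshr and Amh had 0 counts in library 86, Foxl2 and Cyp19a1 stood at 0.42 CPM and Lhcgr at 4.63 CPM. In the other kept libraries the median was 36.1 CPM for Cyp19a1 and 0 for the rest of these. Serpine2, high in library 86, had a median of 369 CPM in the others. Its most abundant genes were Spp1 at 16550, Ftl1 at 7181 and Fth1 at 6064 CPM, with Ovgp1, an oviduct gene, at 5632 CPM; a source in the oviduct and a biological one were not tested.

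Library 61, labelled wild-type 2-cell, had the highest share of those markers among the kept libraries, 1.14% of its counts, and was led by Spp1 at 23820, Ephx2 at 6625 and Actb at 5319 CPM. Unlike library 86 it held Mos, at 200.6 CPM, and Padi6, at 775 CPM. The filter had left out library 58, labelled wild-type 2-cell, with 167079 counts. It was led by Spp1 at 38560 CPM, with Timp1 at 1023 CPM and no counts of Padi6, Mos, Gdf9, Oosp1 or Cyp11a1. Library 13, labelled wild-type oocyte and also left out, held 286318 counts. It was led by Ovgp1 at 16250 CPM, with Gdf9 at 10.48 CPM and no counts of Padi6, Mos or Timp1.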
